A study of Mus musculus with 4 samples.

How the data were processed

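ATAC-seq, in which the Tn5 transposase inserts adapters into accessible DNA, was carried out on CD8+ T cells of BALB/c mice. The series title describes the cells as tumour-infiltrating. The labels give 4 libraries, 1 per condition: unstimulated or stimulated cells, each untreated or treated with phenelzine. Stimulation was with phorbol myristate acetate (PMA) and ionomycin for 2 h. Phenelzine is a monoamine oxidase inhibitor that also inhibits the histone demethylase LSD1, the product of Kdm1a. The design text of the series states that the samples are individual ones without replicates. The tumour and any sort of the cells are not given in the sources used here.

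Per the submitters' processing notes, Trimmomatic 0.33, Bowtie2 2.2.5, Picard, MACS2 and HOMER were used with the mouse genome mm10. The other versions, the parameters and the filters are not given in the sources used here. A list of broad peaks per library was the deposited result, with peaks called in each library on its own. The score that the authors deposited was 10 times the −log10 q-value, rounded down, in 100% of peaks of 3 lists and 99.98% of the stimulated untreated list. The deposited fold enrichment was the peak's pileup over local background, as a ratio. The deposited p-value and q-value columns were on the −log10 scale. Fold enrichment and −log10 q belong to a peak's own list, so they were used here only to describe and rank peaks within a list. The peak names carry the tags less120 and bedpe4macs, whose meaning the sources used here do not spell out. If the first is an upper limit on fragment length in bp, the lists describe short fragments only, and every peak count and region presence refers to these.

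Total reads per library are not in the lists. Depth was therefore described by the background coverage that each list implied. It was solved from the most frequent pair of fold enrichment and −log10 p, taking the fold as (pileup + 1) over (background + 1) and p as a Poisson tail. Between 107 and 190 peaks per list shared that pair. Tested on simulated data, this step returned the planted background within 0.00035%. Those data were built with the same formulas, so this checks the calculation only and not whether the value measures depth.

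Coordinates are mm10, counted from 1. Peaks on chromosomes 1 to 19 and X were used, and the few on Y were set aside. The 4 lists were merged into regions wherever peaks overlapped by at least 1 bp, and a list held a region if it had a peak in it. Genes were the 21627 protein-coding genes of the mouse gene table for the same build. That table held no strand, no exons and no sequence. The promoter window of the plan was therefore replaced by a gene end window, 1 kb on either side of either end of a gene, so start and end sites are not separated. The nearest gene was found by either end in place of the start site. Of the 38 variations of settings laid out, 5 were not run for this reason: 4 for motif shares and 1 for a narrower promoter window. Motif shares were left out altogether.

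Each contrast between a first and a second list gave the regions held by only the first, only the second or both. The 4 contrasts were stimulation in untreated cells, stimulation in phenelzine-treated cells, phenelzine in unstimulated cells and phenelzine in stimulated cells. With 1 library per condition no test between conditions was made, and no p-value was computed. Shares have exact (Clopper-Pearson) 95% intervals, which cover counting error only and not the variation between animals or libraries. Counts of regions by presence pattern were set beside 100 simulated draws with seed 1. In each draw a region kept its number of lists, and the lists were drawn with weights matching the list sizes. Tested on simulated data, merging gave 100% of 500 regions their planted pattern. Without any planted pairing, 0 of 20 data sets lay above the simulated range for lists paired by stimulation.

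The locus of a gene was its body with 20 kb on either side. For each contrast, 17 gene lists with 206 genes, all matched to the table, were scored by the mean difference in regions per locus, first minus second. There were 11 lists of T cell, drug target and housekeeping genes: immediate early and AP-1 genes, cytokines and chemokines, cytotoxic granule and killer receptor genes, activation receptors, inhibitory receptors and exhaustion genes, naive and memory genes, effector transcription factors, the NF-kB and NFAT pathway, T cell receptor and CD8 identity genes, LSD1 complexes with monoamine oxidases, and housekeeping genes. A further 6 lists held markers of other cells: B cells, myeloid cells, CD4 and regulatory T cells, NK cells, epithelial tumour cells, and stroma with endothelium. Each score was placed as a percentile among 10000 random lists of the same number of genes, matched on the number of regions in the locus over the 4 lists. A region in the loci of several list members was counted for each of them, which applied to the cytokine list and the T cell receptor and CD8 identity list. The percentile is a description, and values below 2.5 or above 97.5 are pointed out. Over 68 placements, 3.4 are expected outside these limits by chance. Tested on simulated data, 4% of 200 random lists of 13 genes lay outside. With 1 region added per member in the first list, 96% of 50 lists lay above 97.5.

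Genes are named by a rule fixed, like the lists, the contrasts and most of the settings varied, before the data were examined. Named were the 6 genes with the highest and the 6 with the lowest net difference in regions, pseudogenes and unnamed models left out, and the gene nearest to the 4 regions with the highest −log10 q held by only 1 side. To these came up to 4 members per gene list with a net difference of at least 2, and a fixed set that is always given: Ifng, Tnf, Il2, Gzmb, Prf1, Pdcd1, Havcr2, Tox, Tcf7, Il2ra, Fos, Junb, Egr2, Nr4a1, Cd3e, Cd8a, Kdm1a, Maoa, Maob and Actb. Some genes that the rule names are not reported. Genes outside the rule were chosen after their values were seen: Cd3d, Cd3g, Cd5, Ccr7 and Id3, some markers of other cells (Cebpa, Cebpb, S100a8, Zbtb7b, Csf1r, Itgam, Adgre1 and Mpo), the genes at regions held by a single pair of lists, and those nearest to the strongest shared regions.

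The settings varied by plan were peaks with −log10 q of at least 3, lists reduced to the 6519 peaks with the highest −log10 q, peaks covering at least 0.5 of a region, merging of peaks up to 500 bp apart, and loci of 5 kb or 50 kb on either side. Chosen after seeing the data were lists scaled to the lowest background coverage, keeping peaks with a scaled −log10 p of at least 4.40, regions with a fold of 20 or more left out, and a gene end window of 100 bp. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.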

Results

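Accessible DNA was compared in CD8+ T cells of BALB/c mice under 4 conditions, with 1 library each and no replicates. The unstimulated untreated list held 6525 peaks, the unstimulated phenelzine list 7938, the stimulated untreated list 10414 and the stimulated phenelzine list 9331. On chromosomes 1 to 19 and X the numbers were 6519, 7929, 10405 and 9322, in the same order. These peaks covered 1137.68, 1420.3, 1942.94 and 1634.87 kb. Median widths were 139, 142, 150 and 140 bp. The background coverage implied by the lists was a pileup of 0.392, 0.471, 0.493 and 0.489, so the unstimulated untreated library had the lowest depth by this measure. Median fold enrichments were 5.03, 4.82, 4.86 and 4.78, and median −log10 q 2.95, 2.69, 2.93 and 2.68. The share of peaks at gene ends was 64.9% (95% interval 63.7 to 66.0) in unstimulated untreated, 59.9% (58.8 to 61.0) in unstimulated phenelzine, 52.9% (51.9 to 53.9) in stimulated untreated and 54.97% (53.9 to 56.0) in stimulated phenelzine cells. Among the 6519 peaks with the highest −log10 q of each list the shares of the last 3 were 65.7%, 66.7% and 65.7%, so the lower shares of the longer lists came with their weaker peaks. Gene-end peaks covered 4998, 5543, 6340 and 5933 protein-coding genes.

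**Figure D1:**
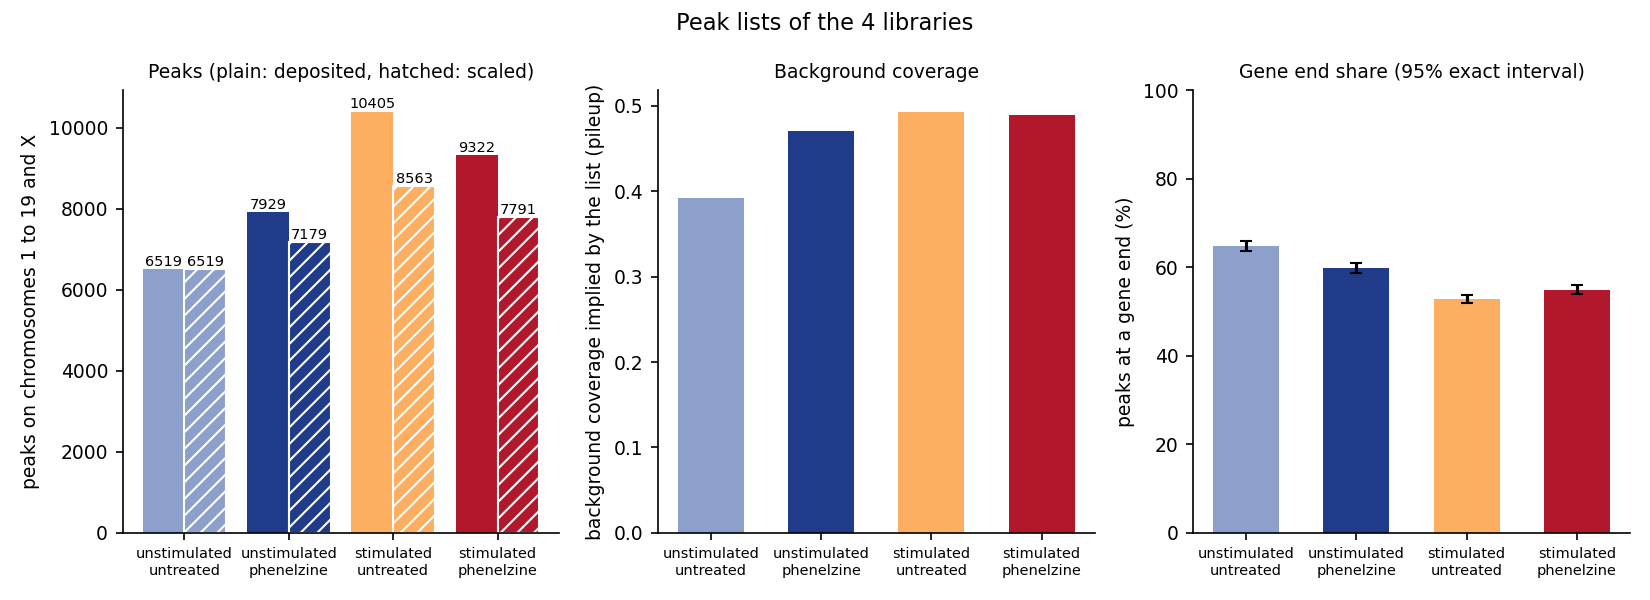
Bars for each of the 4 libraries give the number of peaks (plain as deposited, hatched after scaling to the lowest background coverage), the background coverage implied by the list (pileup), and the percent of peaks at gene ends with exact 95% intervals. The stimulated untreated list was the longest with 10405 peaks and had the lowest gene-end share, 52.9%.

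The lists merged into 15237 regions. A core of 4085 regions (26.8%) was held by all 4 lists, with 77.0% at gene ends, while 6645 (43.6%) were held by 1 list alone, with 22.3% at gene ends. Genes with a gene-end peak in any list numbered 7542 of 21627 (34.9%). Housekeeping genes were well covered, with gene-end peaks at 10 of 13 members. Actb, which encodes beta-actin, was not among them, though each list held regions in its locus. Immediate early and AP-1 genes, which T cells use within minutes of activation, had gene-end peaks at 14 of 20 members, and the NF-kB and NFAT pathway at 8 of 13. Coverage was low for T cell receptor and CD8 identity genes, with 2 of 15 members, Cd3d and Cd5. Only 2 of 15 cytokine genes, 2 of 12 cytotoxic genes, 2 of 12 activation receptors and 2 of 12 naive and memory genes had one. For inhibitory receptors and exhaustion genes the count was 4 of 12, for effector transcription factors 3 of 10, and for LSD1 complexes with monoamine oxidases 6 of 14. No region in any list fell in the loci of Ifng and Il2, which encode effector cytokines, or Gzmb and Prf1, which encode granzyme B and perforin. The same was true of Cd8a, Il2ra, Tox and Maob. The inhibitory receptor gene Havcr2 had 1 region in each list.

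The first comparison asked which regions were accessible after stimulation without phenelzine. Nr4a3, an orphan nuclear receptor gene induced by antigen receptor signals, had 3 regions in its locus in stimulated untreated cells and 0 in unstimulated untreated cells. The region at its gene end, chromosome 4 from 48045015 to 48045129, had a fold enrichment of 6.67 and −log10 q 6.51. Fos, which encodes an AP-1 subunit, had 4 regions against 2, with a gene-end peak at chromosome 12 from 85473539 to 85473859 (fold 5.18) in the stimulated untreated list alone. Myc, a driver of growth after activation, had 3 against 1. Nfkbie, which encodes an inhibitor of NF-kB, had 4 against 1, and Nfatc1, a calcium-responsive transcription factor gene, 3 against 1.

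In untreated cells 5085 regions were held by the stimulated list alone, 43.9% (95% interval 43.0 to 44.8) of the 11576 in either list. The unstimulated list alone held 1193 (10.3%, 9.76 to 10.9), and both held 5298. Shared regions lay at gene ends in 71.7%, and those of the stimulated list alone in 33.4%. The highest net difference was at Sfi1, a centrosomal gene on chromosome 11, with 19 regions against 10. Atxn7l1 had 8 against 1, and the neighbouring histone genes H2ac10 and H3c8 on chromosome 13 had 9 against 3. Zfp608, a zinc-finger gene, and Cdk9, the kinase that releases paused RNA polymerase, each had 6 against 0. The lowest net differences, −2, were at Mycbp2, Dolk, Nup188, Phyhd1, Ccdc30 and Cul7. Dolk had 0 regions against 2. The strongest region of the stimulated list alone lay inside Arhgef4 on chromosome 1 from 34753041 to 34753110, with fold 9.89 and −log10 q 13.02. Others lay at Rpl37a and Yars2 and near Fcgr4. In the unstimulated list the strongest lay near Tmem125, Trmt61a, the class I gene H2-Q7 and the mitotic kinesin gene Kif11.

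By gene list, 9 of 20 immediate early and AP-1 genes had more regions after stimulation in untreated cells, 1 fewer and 10 the same number, at percentile 74.0 of random lists. Of the cytokine genes 5 of 15 had more and 0 fewer (percentile 90.3). Activation receptors had 2 with more, Cd44 (2 against 0) and the transferrin receptor gene Tfrc (3 against 1), at percentile 89.2. In the NF-kB and NFAT pathway 7 of 13 had more and 2 fewer (percentile 59.4). Effector transcription factors had 4 with more and 2 fewer (64.1), among them Hif1a with 2 against 0 and Zeb2 with 3 against 1. T cell receptor and CD8 identity genes had 6 with more and 0 fewer (69.8). Of these, Cd3e (1 against 0), Cd3d and Cd3g owed theirs to the same region on chromosome 9 from 44986550 to 44986741, so the 6 genes stood for 4 distinct regions. The 5 cytokine genes likewise stood for 4 distinct regions. For cytotoxic genes 2 had more, with Srgn, the granule proteoglycan gene, at 4 against 2 (54.9). Inhibitory receptors and exhaustion genes had 1 with more and 2 fewer, and their mean difference of −0.167 regions lay at percentile 0.645. Cd244a, an inhibitory receptor gene, had 0 against 2, while Pdcd1, which encodes PD-1, had 1 in each. Naive and memory genes had 2 with more and 3 fewer (3.05), with Tcf7 at 0 against 1. LSD1 complexes with monoamine oxidases lay at 8.38 with Kdm1a at 0 in both and Maoa at 1 in both, and housekeeping genes at 23.3, with Actb at 4 against 2. Junb had 3 against 2, Nr4a1 3 against 2, and Egr2 1 in each, while Tnf had 0 in both.

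With −log10 q of at least 3, 2572 regions were held by the stimulated list alone and 696 by the unstimulated list alone. With lists of equal size the numbers were 2131 and 2118. Lists cut to the same number of peaks leave nearly equal numbers on either side by construction. This balance therefore does not show that the difference between the lists was due to their size. The placement of the inhibitory receptor list moved to percentile 5.86 with −log10 q of at least 3 and to 8.82 with loci of 50 kb.

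The next comparison asked the same of cells treated with phenelzine. Nfkbie again had 4 regions in stimulated cells against 1 in unstimulated cells. Nfatc2, which encodes the NFAT factor of resting T cells, and Rcan1, a calcineurin regulator and NFAT target gene, each had 3 against 1. The adhesion receptor gene Cd44 had 3 against 1 and the AP-1 gene Fosb 5 against 3. Against these, the early growth response gene Egr3 had 0 against 2, the ectonucleotidase gene Entpd1 0 against 2, and Srgn 1 against 3.

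In phenelzine-treated cells 3701 regions were held by the stimulated list alone, 31.9% (31.1 to 32.8) of the 11594 in either list. The unstimulated list alone held 2309 (19.9%, 19.2 to 20.7), and both held 5584. Gene-end shares were 31.4% for the stimulated list alone and 70.6% for both. The highest net differences were at Arhgap42 (9 against 3), Ttll12 (5 against 0), Mid1 (9 against 4), Mcat and the mitochondrial translocator gene Tspo (each 4 against 0) and Lrsam1 (5 against 1). The lowest were at Macrod2, an ADP-ribosylhydrolase gene (4 against 9), the corepressor gene Lcor (0 against 4), Ube2g1 and Pisd (each 1 against 4), Prdm11 (0 against 3) and H2ac7 (4 against 7). Among the strong regions of the stimulated list alone, one lay 62 bp from the end of Mprip. Others lay 319502 and 313052 bp from their nearest gene, Alkbh8, at the start of chromosome 9. Those of the unstimulated list alone included Gtpbp10 and the splicing factor gene Srsf11, and a region 831238 bp from Tyrp1.

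By gene list, the NF-kB and NFAT pathway had 6 of 13 members with more regions after stimulation in phenelzine-treated cells and 1 fewer, at percentile 97.6. Cytotoxic genes had 0 of 12 with more and 2 fewer, at percentile 2.17. Immediate early and AP-1 genes had 8 with more and 4 fewer (percentile 58.5), with Egr2 at 1 against 0, Fos at 1 against 2 and Nr4a1 at 2 against 3. Activation receptors had 2 with more and 0 fewer (92.4). For naive and memory genes 4 had more and 1 fewer (86.7), with Tcf7 at 1 against 0. Cytokine genes had 2 with more and 3 fewer (19.5), with Tnf at 0 against 1. T cell receptor and CD8 identity genes had 2 with more and 4 fewer (9.60), among the latter Cd3e, Cd3d and Cd3g through that same region. Counted once, distinct regions of this list numbered 2 for the stimulated list alone and 2 for the unstimulated list alone. Inhibitory receptors had 3 with more and 1 fewer (48.5), with Pdcd1 at 2 against 1. Effector transcription factors had 2 with more, including Stat4 at 3 against 1, and 2 fewer, including Zeb2 at 1 against 3 (31.0). LSD1 complexes had 2 with more, including Hdac1 at 2 against 0, and 2 fewer (44.5), with Kdm1a at 1 in both and Maoa at 0 in both. Housekeeping genes lay at 47.5, with Actb at 4 against 3, and Junb had 3 in both.

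With −log10 q of at least 3 the numbers were 1683 for the stimulated list alone and 1070 for the unstimulated list alone. The NF-kB and NFAT list moved to percentiles between 61.6 and 97.1 under 4 alternatives. The cytotoxic list moved to 3.80 with lists of equal size, 8.70 with loci of 50 kb and 2.58 with lists scaled to the lowest background coverage.

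Both arms were then set side by side to ask whether stimulation opened the same regions with and without phenelzine. Of the regions in both stimulated lists and neither unstimulated one, some lay in the loci of list genes, and those named here were chosen after their values were seen. Prdm1, which encodes the effector regulator Blimp-1, had one at its gene end on chromosome 10 from 44529499 to 44529617, with −log10 q 6.82 in stimulated untreated and 1.46 in stimulated phenelzine cells. The gene-end region of Nr4a3 named above belonged to this group, with −log10 q 6.51 and 2.58. Nfkbie had 2 such regions, the one at its gene end lying on chromosome 17 from 45563833 to 45563976 (4.25 and 1.99). Nr4a2, a relative of Nr4a3, had one at its gene end (2.27 and 2.68). The NF-kB signalling adaptor gene Traf1, Nfatc2 and Rcan1 had one each, as did Zeb2, the housekeeping genes Actb and Polr2a, the neutrophil receptor gene Csf3r and the stromal gene Prrx1. These were 12 of the 206 list genes (5.83%, 3.05 to 9.95), against 1201 of all protein-coding genes (5.55%), so list genes did not stand out.

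In all, 896 regions were held by both stimulated lists and neither unstimulated list. They made up 17.6% (16.6 to 18.7) of the 5085 regions of the stimulated untreated list that the unstimulated untreated list lacked, and 24.2% of the corresponding 3701. Of these 5085 regions, 1840 (36.2%) were held by the stimulated phenelzine list, 1500 (29.5%) by the unstimulated phenelzine list and 2689 (52.9%) by no other list. Random draws that kept the list sizes and the number of lists holding each region gave a mean of 878.74 such regions (range 817 to 928), and the observed 896 lay within that range. These draws start from the observed amount of sharing and describe only which lists share. Independent placement of the 5085 and 3701 regions among all 15237 gave 1235.12. The 15237 leave out places that no list held, which raises this value. It therefore does not show that shared gains were rarer than by chance. Counting all regions in pairs of lists alone, 1019 fell to pairs by stimulation (drawn range 956 to 1057), 659 to pairs by phenelzine (615 to 756) and 776 to crossed pairs (708 to 823). The single pattern outside its drawn range was unstimulated untreated with both phenelzine lists, with 181 regions (201 to 266).

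**Figure D2:**
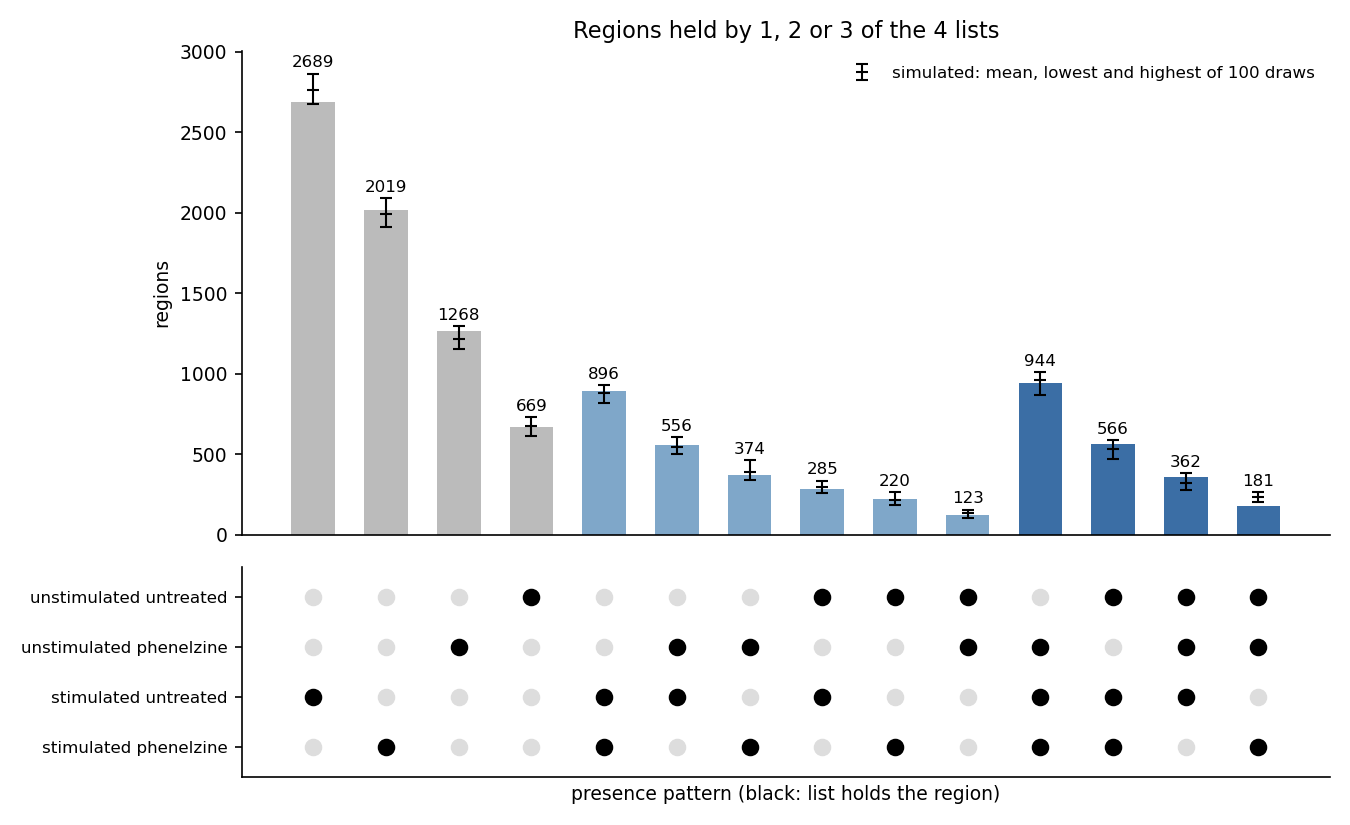
Bars give the number of regions held by each combination of 1, 2 or 3 lists (black dots), and whiskers the mean, lowest and highest of 100 simulated draws. Regions held by both stimulated lists alone numbered 896, within the drawn range of 817 to 928.

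The effect of phenelzine was first examined in unstimulated cells. Kdm1a, the gene of the LSD1 demethylase that phenelzine inhibits, had 1 region with phenelzine and 0 without, while Maoa, the gene of a monoamine oxidase it also inhibits, had 0 against 1. Bach2, a repressor gene that holds T cells in a resting state, had 0 against 3, all within its body. Their −log10 q was 1.99, 1.82 and 3.16, and only the last was also held by the stimulated untreated list. Klf2, a quiescence factor gene, had 1 against 3. The naive T cell gene Tcf7 had 0 against 1. Hif1a, the hypoxia response factor gene, had 3 against 0, and Bhlhe40, an effector regulator gene, 3 against 1. Going the other way, Ccr7 and Id3 of the naive and memory list each had 1 against 0. Stat4 of the effector list had 1 against 2.

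With phenelzine 3142 regions were held by the treated list alone, 32.6% (31.7 to 33.6) of the 9633 in either list, and the untreated list alone held 1740 (18.1%, 17.3 to 18.8). Both lists held 4751, with 74.3% at gene ends. With −log10 q of at least 3 the phenelzine list alone held 1411 and the untreated list alone 1165. With lists of equal size each held 2116, a balance set by the equal sizes. The highest net differences were at Macrod2 (9 against 2), the angiopoietin gene Angpt1 and Fndc3b (each 6 against 1), Lcor (4 against 0), Arid5b (5 against 1) and Atxn1 (4 against 0). The lowest, −3, were at Btd, Bach2, Abca7 and Anxa11 (each 0 against 3) and at the cystine transporter gene Slc7a11 and Nfatc2 (each 1 against 4). The strongest regions of the treated list alone were at the start of chromosome 9 from 3027109 to 3027176 (fold 9.72, −log10 q 46.4) and far from Tyrp1 (fold 2.94, −log10 q 23.9). Their −log10 q was high for their fold, since the region at Rpl37a in the same list had fold 8.73 and −log10 q 10.2. No repeat or mapping filter was applied here, so these regions were not shown to mark accessible DNA. The untreated list alone held strong regions at Trmt61a, 165527 bp from Egln3, at Haus5 and in Tgif1.

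Naive and memory genes had 2 of 12 members with more regions with phenelzine in unstimulated cells and 4 fewer, and their mean difference of −0.417 lay at percentile 0.075. The percentile stayed at 2.19 or below under the alternatives run. Effector transcription factors had 3 of 10 with more, Hif1a, Bhlhe40 and Zeb2 (3 against 1), and 1 fewer, at percentile 98.2. Immediate early and AP-1 genes had 6 with more and 5 fewer (16.6), with Atf3 at 1 against 3, Fos at 2 in both, Junb at 3 against 2, Nr4a1 at 3 against 2 and Egr2 at 0 against 1. Cytokine genes had 3 with more, including Tnf at 1 against 0, and 2 fewer (51.8). Cytotoxic genes and activation receptors each had 2 with more and 0 fewer (69.6 and 80.9). Inhibitory receptors had 1 with more and 2 fewer (15.8), with Pdcd1 at 1 in both. The NF-kB and NFAT pathway had 3 with more and 2 fewer (12.8). T cell receptor and CD8 identity genes had 5 with more, among them Cd6 at 2 against 0 and the Cd3 genes through their shared region, and 2 fewer (82.2). LSD1 complexes had 5 with more and 3 fewer (55.8), and housekeeping genes 2 with more and 3 fewer (21.1), with Actb at 3 against 2. The effector factor list moved to percentile 64.0 with −log10 q of at least 3, 95.4 with loci of 5 kb and 97.2 with scaled lists.

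**Figure D3:**
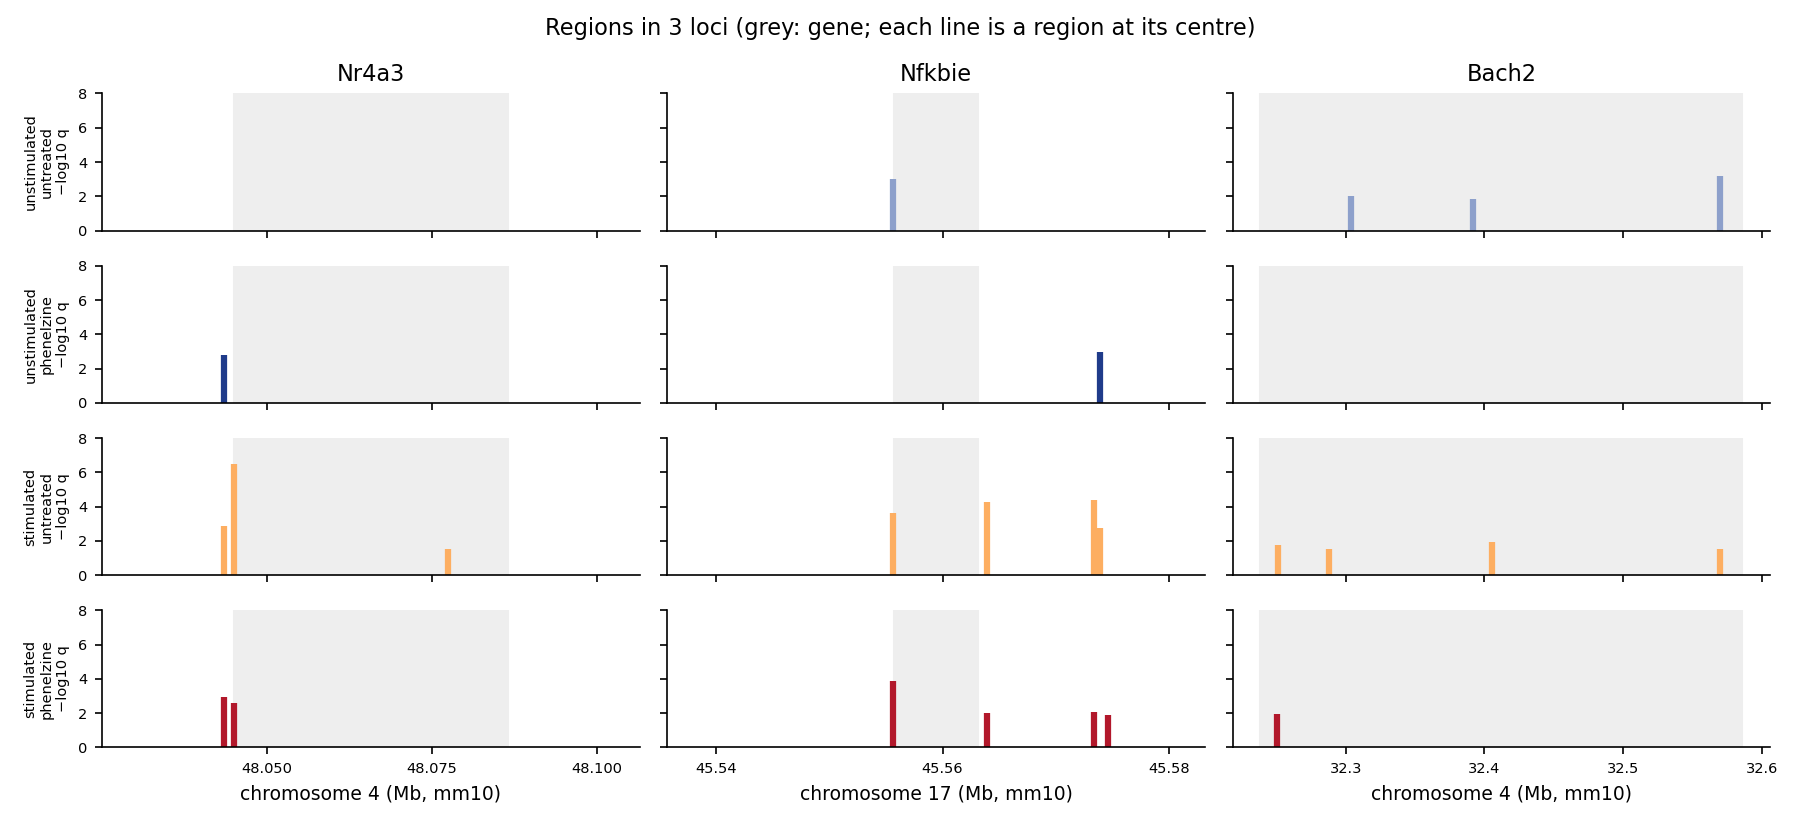
Lines mark the regions each of the 4 libraries held in the loci of Nr4a3, Nfkbie and Bach2 (grey, gene body), by position in Mb on mm10 and by −log10 q within that list. Bach2 had 3, 0, 4 and 1 regions in unstimulated untreated, unstimulated phenelzine, stimulated untreated and stimulated phenelzine cells. Only the region from 32570110 to 32570222 was held by both untreated lists.

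In stimulated cells, the comparison asked which regions phenelzine treatment accompanied after PMA and ionomycin. Fos had 1 region with phenelzine against 4 without, Egr3 0 against 2, and Srgn 1 against 4. Bach2 had 1 against 4 and Nfatc1 1 against 3. The exhaustion-associated gene Tox2 had 2 against 0, Cd244a 2 against 0, and Pdcd1 2 against 1, while Entpd1 had 0 against 2. Kdm1a had 1 against 0, its corepressor partner gene Rcor3 2 against 0, and Maoa 0 against 1.

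Here 2794 regions were held by the phenelzine list alone, 21.2% (20.5 to 21.9) of the 13177 in either list, and 3892 by the untreated list alone (29.5%, 28.8 to 30.3). Both lists held 6491, with 67.0% at gene ends. The highest net differences were at Tgfbr3, which encodes a TGF-beta co-receptor (5 against 0), the stress sensor gene Atf6 (6 against 2), Fbn1 (4 against 0), the T cell transcription factor gene Ets1 (7 against 3) and the histone genes H2ac4 and H2bc3 (8 against 4). The lowest were at the formin gene Fmnl2 (3 against 9), Sfi1 (14 against 19), H2ac10 and H3c8 (4 against 9), and Slx4ip and Aopep (each 1 against 6). Strong regions of the phenelzine list alone lay at Pacc1 and the small ribonucleoprotein gene Snrpf, and those of the untreated list alone at Arhgef4, Zfp983, Rtcb and Zfp131.

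Cytokine genes had 0 of 15 members with more regions with phenelzine in stimulated cells and 5 fewer, at percentile 3.04. A region shared by neighbouring genes was counted for each of them. Counted once, distinct regions numbered 1 for the phenelzine list alone and 5 for the untreated list alone. The mean difference was then −0.267 in place of −0.333, and its percentile was not computed. Immediate early and AP-1 genes had 2 with more, including Fosb at 5 against 3, and 8 fewer (8.51). Nr4a1 was among the latter with 2 against 3, while Junb had 3 and Egr2 had 1 in both. Cytotoxic genes had 1 with more and 3 fewer (6.79), and T cell receptor and CD8 identity genes 1 with more and 5 fewer (18.7), Cd3e, Cd3d and Cd3g again through their shared region. Inhibitory receptors had 3 with more and 2 fewer (90.3), LSD1 complexes 3 with more and 2 fewer (90.2), and effector transcription factors 3 with more and 1 fewer (90.9), with Stat4 at 3 against 1 and Zeb2 at 1 against 3. Activation receptors had 2 with more and 1 fewer (82.4), the NF-kB and NFAT pathway 3 with more and 2 fewer (76.0), naive and memory genes 2 with more and 1 fewer (46.1), with Tcf7 at 1 against 0, and housekeeping genes 0 with more and 2 fewer (46.3), with Actb at 4 in both. Tnf had 0 in both. With lists of equal size 2108 regions were held by the phenelzine list alone and 2113 by the untreated list alone, nearly equal by construction. The cytokine list then lay at percentile 2.10.

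**Figure D4:**
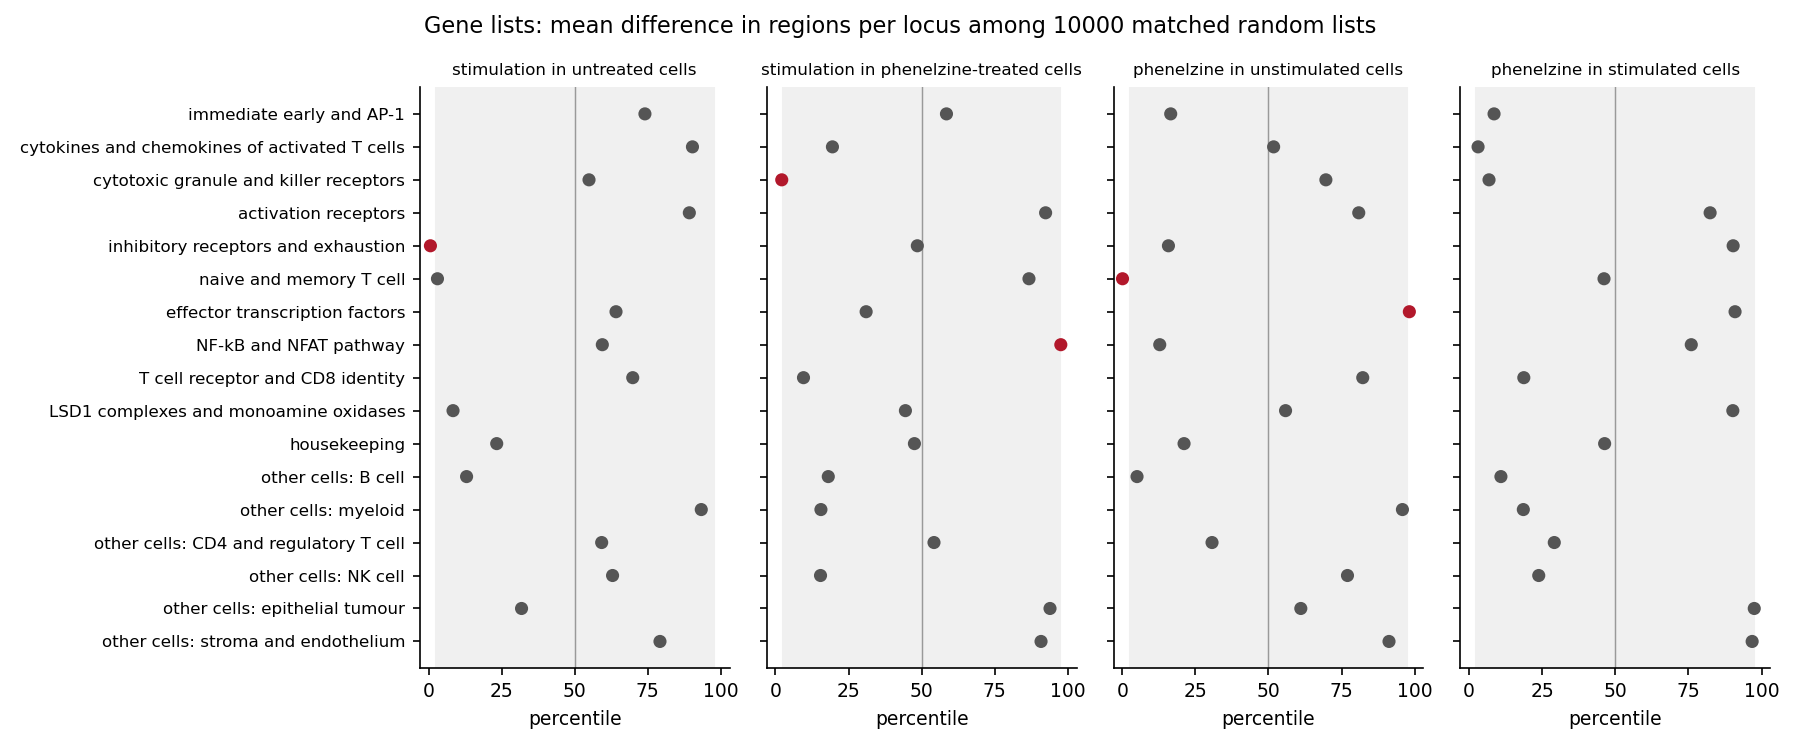
Percentile of each gene list's mean difference in regions per locus among 10000 random lists, for the 4 contrasts, with a point per list and a grey band for the central 95%. Of 68 placements, 5 (red) lay outside the band, where 3.4 are expected by chance.

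Markers of other cell types were counted in the same way. Myeloid genes had gene-end peaks in any list at 5 of 13 members: Spi1, Cd14, Cebpa, Cebpb and S100a8. By library, 0 had one in unstimulated untreated, 1 in unstimulated phenelzine, 5 in stimulated untreated and 1 in stimulated phenelzine cells. The count of 5 was 1 with −log10 q of at least 3, 2 with lists of equal size and 3 with scaled lists. In the contrasts this list lay at percentile 93.3 for stimulation in untreated cells and 15.6 in phenelzine-treated cells, and at 95.8 for phenelzine in unstimulated and 18.5 in stimulated cells. Fcgr3, an Fc receptor gene, had 0, 3, 4 and 2 regions in unstimulated untreated, unstimulated phenelzine, stimulated untreated and stimulated phenelzine cells, Cd14 had 3, 5, 6 and 3, Cd68 had 2, 4, 3 and 4, and Spi1 had 1, 0, 2 and 2. Among CD4 and regulatory T cell genes Zbtb7b alone had a gene-end peak, in each list, and Gata3 had 1, 0, 2 and 0 regions. No gene-end peak lay at the B cell, NK cell, epithelial or stromal markers in any list. Percentiles in the order of the contrasts above were 13.01, 18.1, 5.04 and 10.9 for B cells, 59.2, 54.2, 30.7 and 29.1 for CD4 and regulatory T cells, and 62.9, 15.4, 77.0 and 23.8 for NK cells. For epithelial genes they were 31.8, 93.9, 61.1 and, in the last contrast, the upper limit of the central 95%, and for stroma and endothelium 79.2, 90.8, 91.2 and 96.8. The NK marker Tyrobp had 1, 2, 1 and 0 regions, and the stromal gene Prrx1 0, 1, 1 and 3.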

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

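All tests in this part that weigh an explanation were chosen only after the result was seen.

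The number of peaks differed in opposite directions with phenelzine. In unstimulated cells the phenelzine list had 1410 more peaks than the untreated list, and in stimulated cells the value was −1083, a difference of 2493. With 1 library per condition this difference was not tested.

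Several gene lists also had mean differences in regions per locus of opposite sign in the 2 arms of a contrast, none of them tested against variation between animals. For stimulation, cytokine genes had 0.333 in untreated and −0.0667 in phenelzine-treated cells, and for phenelzine 0.0667 in unstimulated and −0.333 in stimulated cells, a difference of 0.4 either way. Cytotoxic genes had 0.25 and −0.25 for stimulation, and 0.167 and −0.333 for phenelzine, differing by 0.5. Inhibitory receptors and exhaustion genes had −0.167 and 0.0833 for stimulation, and −0.0833 and 0.167 for phenelzine, differing by −0.25. Naive and memory genes had −0.0833 and 0.25 for stimulation, differing by −0.333. T cell receptor and CD8 identity genes had 0.4 and −0.133 for stimulation, and 0.267 and −0.267 for phenelzine, differing by 0.533. A single region shared by Cd3e, Cd3d and Cd3g, with −log10 q of 1.55 and 1.59, was counted for each of the 3 genes. With each region counted once, this list had 0.267 and 0 for stimulation, and 0.133 and −0.133 for phenelzine, differing by 0.267. The cytokine list then differed by 0.333. Myeloid markers had 0.769 and −0.0769 for stimulation, and 0.538 and −0.308 for phenelzine, differing by 0.846. NK cell markers had 0.143 and −0.143 for both contrasts, differing by 0.286. Both contrasts of a list compare the same 4 libraries, so the paired entries are 1 difference each and not separate findings.

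Peaks on chromosome Y were left out of the comparisons. There were 6 in the unstimulated untreated list, 9 in the unstimulated phenelzine list, 9 in the stimulated untreated list and 9 in the stimulated phenelzine list. All of them lay between 90738186 and 90813662.

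The stimulated untreated list was longer than the unstimulated untreated list, by a ratio of 1.60 (95% interval 1.55 to 1.65 for counting error), while background coverage differed by a ratio of 1.26. After scaling to the lowest background coverage the ratio was 1.31 (1.27 to 1.36), with intervals for counting error that leave out the error of the scaling and the spread between libraries, so coverage stays open as a cause. Stimulation that opened a shared set of regions may contribute, yet 1019 regions were paired by stimulation, within the drawn range of 956 to 1057. On simulated data such pairing passed the range in 1 of 20 data sets with 400 planted regions, 14 with 800 and 19 with 1600. Each planted region was detected in each stimulated list with the same fixed probability, and other probabilities were not tried. The draws were also weighted by the observed list sizes, which such a set would itself increase. A count within the drawn range therefore excludes no size of shared set. The list ratio in untreated cells was 1.36 (1.3004 to 1.42) times that in phenelzine-treated cells, and with single libraries stimulation, coverage and other differences between libraries cannot be told apart.

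For phenelzine the ratio of list sizes in unstimulated cells was 1.22, or 1.10 (1.06 to 1.14) after scaling, against a background ratio of 1.20. In stimulated cells it was 0.896, or 0.910 (0.882 to 0.938) after scaling, against a background ratio of 0.992. These intervals cover counting error alone, so coverage stays open as a cause in either state. A set of regions opened by phenelzine in both states could exist, but 374 such regions lay within the drawn range of 340 to 462. Such a set, coverage and variation between single libraries cannot be told apart, because each state has 1 library with the drug.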

How the results depend on the processing

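Lists scaled to the lowest background coverage, regions with a fold of 20 or more left out and the gene end window of 100 bp were tests chosen only after the results were seen. The other alternatives were planned. Of all values recomputed, 511 kept their side of a limit or stayed within their interval or 1.5 times their count, 38 moved, 15 passed a percentile limit they had not passed, 12 no longer passed one and 0 changed sign as a called value. For those below, the cause was not tested unless it follows from how the alternative was built.

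With −log10 q of at least 3 the lists held 3179, 3427, 5057 and 4039 peaks in unstimulated untreated, unstimulated phenelzine, stimulated untreated and stimulated phenelzine cells, since weaker peaks were removed. Regions of 1 side alone numbered 2572 and 696 for stimulation in untreated cells, 1683 and 1070 in phenelzine-treated cells, 1411 for the phenelzine list in unstimulated cells, and 1115 and 2132 for the phenelzine and untreated lists in stimulated cells. Gene-end shares were 78.0%, 77.6%, 72.1% and 75.0%. With lists of equal size stimulation gave 2131 and 2118 regions in untreated cells and 2144 for the stimulated list in phenelzine-treated cells. The untreated list alone held 2113 in stimulated cells. Equal sizes force nearly equal numbers on either side of a contrast, so these counts do not test its direction. The share of stimulation-gained regions found in both arms was 15.6%. Gene-end shares were 65.7% in both phenelzine lists and 66.7% in stimulated untreated cells. The lower gene-end share of the longer stimulated untreated list was therefore not kept at equal size. Scaled lists gave shares of 62.8%, 59.3% and 60.5% in unstimulated phenelzine, stimulated untreated and stimulated phenelzine cells, and the window of 100 bp gave 54.2%, 49.8%, 44.1% and 45.8%.

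Of the 5 placements outside the central 95%, that of the naive and memory list with phenelzine in unstimulated cells stayed outside in all settings run. The inhibitory receptor list for stimulation in untreated cells lay at 5.86 with −log10 q of at least 3 and 8.82 with loci of 50 kb. The cytotoxic list for stimulation in phenelzine-treated cells lay at 3.80 with equal sizes, 8.70 with 50 kb and 2.58 with scaled lists. The NF-kB and NFAT list there lay at 80.3 with −log10 q of at least 3, 61.6 with equal sizes, 97.1 with 5 kb and 93.8 with 50 kb. Effector transcription factors with phenelzine in unstimulated cells lay at 64.0 with −log10 q of at least 3, 95.4 with 5 kb and 97.2 with scaled lists.

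Other lists passed a limit in some settings. For stimulation in untreated cells naive and memory genes lay at 0 with equal sizes and 1.27 with scaled lists. In phenelzine-treated cells activation receptors lay at 99.6 with equal sizes, 97.9 with 5 kb and 99.2 with scaled lists, effector transcription factors at 0.84 with equal sizes, and epithelial genes at 97.52 with 50 kb. With phenelzine in unstimulated cells inhibitory receptors lay at 2.06 with 5 kb and stroma at 99.6 with 50 kb. In stimulated cells cytokine genes lay at 1.52 with −log10 q of at least 3 and 2.10 with equal sizes, activation receptors at 99.3 with −log10 q of at least 3, epithelial genes at 98.8 with 50 kb and 97.8 with scaled lists, and stroma at 99.8 with scaled lists.

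Myeloid genes with a gene-end peak numbered 0 in unstimulated phenelzine cells with −log10 q of at least 3, with equal sizes and with scaled lists. In stimulated untreated cells they numbered 1, 2 and 3 in these settings. CD4 and regulatory T cell genes numbered 0 in either unstimulated list with −log10 q of at least 3. The 4 motif alternatives and the narrower promoter window were not run, because the gene table holds no sequence and no strand. Depth limits what a list can hold. The highest −log10 q of a region over the lists had a median of 1.85 for regions of 1 list alone. For regions of all 4 lists it was 5.65, which is raised because it takes the highest of 4 values. Regions of 1 list alone thus lay at low −log10 q, and a region missing from a list was not shown to be closed.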

Other observations

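All tests in this part were chosen only after the result was seen. Regions held by both phenelzine lists and neither untreated list included the gene end of Kdm1a, the LSD1 gene, on chromosome 4 from 136602702 to 136602832. Its −log10 q was 1.86 in unstimulated and 4.55 in stimulated phenelzine cells. Rcor3, which encodes an LSD1 corepressor partner, had such a region too (3.39 and 1.46). So did the inhibitory receptor gene Lag3, on chromosome 6 from 124919802 to 124919929 (3.17 and 5.11), and Bhlhe40 at its gene end (3.28 and 2.32). Cd44, Tox2, Hif1a, Cd6 and Ccl5 had one each. These belonged to 15 of the 206 list genes (7.28%, 95% interval 4.13 to 11.7), against 562 of all protein-coding genes (2.60%), and the genes were singled out after their values were seen. In the opposite pattern, both untreated lists and neither phenelzine list held a region 1074 bp from Maoa, on chromosome X from 16618487 to 16618624 (2.01 and 2.73). Regions of that kind also lay near Fos (4.14 and 6.72) and in Bach2, Nfatc1 and Gata3, with 8 list genes (3.88%, 1.69 to 7.51) against 430 of all genes (1.99%). In the crossed pairs the shares were 5.34% (2.70 to 9.35) against 3.70% for unstimulated phenelzine with stimulated untreated, and 2.43% (0.793 to 5.57) against 1.40% for the reverse pair. The intervals of these 3 pairs include the share of all genes. List genes were not matched to other genes on locus size or number of regions.

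The strongest regions were shared by the conditions. All 26 regions with a fold of 20 or more were held by all 4 lists, and 2 of them lay at gene ends and 15 outside genes. No repeat or mapping filter was applied to any list here, so these regions were not shown to mark accessible DNA. The strongest lay 35307 bp from Pak3, on chromosome X from 143483009 to 143483109, with folds of 53.4, 57.1, 54.9 and 59.1 in unstimulated untreated, unstimulated phenelzine, stimulated untreated and stimulated phenelzine cells. One near Abcb11 had folds of 52.7, 55.5, 55.1 and 51.8, and one inside Chl1, a neural adhesion gene, 48.6, 48.9, 48.8 and 51.0. None of these genes belongs to the lists of T cell genes used here.

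Few gene-end peaks lay at T cell receptor and CD8 identity genes, with 13.3% of members (1.66 to 40.5) having one in any list, while housekeeping genes had 76.9% (46.2 to 94.96). A candidate explanation is that peaks lie mostly at genes used by many cell types, and pooled markers of other cells had 6 of 58 (10.3%, 3.89 to 21.2). Of these 6, however, 5 were myeloid, and without that list the pool had 1 of 45 (2.22%, 0.0562 to 11.8), nominally below the T cell value with overlapping intervals. DNA of myeloid cells is another candidate explanation, with 38.5% (13.9 to 68.4) of myeloid genes having such a peak, though 4 of these 5 had it in stimulated untreated cells alone and Csf1r, Itgam, Adgre1 and Mpo had no region in any list. The lists are too short to decide, so these explanations cannot be told apart, no sort that would remove such cells is named in the labels, and no biological explanation was tested.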
